A study of Xenopus laevis with 31 samples.

How the data were processed

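Total RNA (10 µg per sample) from 31 Xenopus laevis samples was labelled and hybridised to Affymetrix Xenopus arrays, per the labels' protocols. Per the deposited checklist, 20 µg of labelled cRNA was hybridised at 45 °C, arrays were read on a GeneChip Scanner 3000, and GeneChip Operating Software 1v4 scaled them to a target of 1500 and made the probe-level files. Per the same checklist these were summarised by RMA in GeneSpring 7.1, and the submitters' processing notes also name RMA. The checklist adds a normalization of replicate averages to the stage 11 mean, which the deposited values do not show. It accepts 3' to 5' ratios from 1 to 3 for GAPDH and beta-actin. In the deposited values the GAPDH ratio was over 3 on 30 arrays, and the beta-actin ratio was under 1 on 26 and over 3 on 1.

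The deposited values are linear intensities, 1 per probe set and array (15611 probe sets, 483941 values). Values of 1000 and more were written with a digit-group mark that reads as a decimal point, so that none exceeded 999.9. They were restored before use. The size and written form of a value settled 438140 values (90.5%), and 45181 were assigned from the other values of their probe set. Of the settled values, 16571 lay below 3.5, where every value was taken as 1000 or more, and 0 of these had fewer than 3 decimals. The others were settled by their number of decimals or a final 0. In all, 18127 values (3.75%) were restored to 1000 or more, and decoded intensities ran from 3.52 to 12580. When 5101 settled values, written as 3.5 to 10, were hidden, 5095 were recovered, and 149 of the 150 among them that were 1000 or more. In probe sets holding both forms 115 of 121 were recovered. For 20 probe sets the level stayed open, which leaves their fold changes unaffected. After 120 control probe sets and 41 others with an undecided assignment were left out, 15450 were tested.

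Groups came from the condition named for each sample, and replicate numbers from the labels. Samples pooled embryos of a single mating, but the labels do not say which samples shared one, so p-values measure the spread between these samples. Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per group over all 31 arrays, which left 22 residual degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Tissue, stage and egg comparisons also required a change of 2-fold (1 on the log2 scale). Sets were tested with camera (preset correlation 0.01, and estimated) and Fisher's exact test, with fry where given, and scores per array with exact permutation tests. Probe sets are not independent, so p-values across probe sets describe these arrays. All 42 named changes were smaller with a pseudocount of 16, and signal over background was not analysed here, so folds against low intensities are uncertain in size. Named probe sets are those with the largest changes among calls whose groups do not overlap, at most 2 higher and 2 lower per comparison. Gene names, and the gene lists fixed for this work, were not analysed here, because 0 probe sets could be matched to a gene in the tables used. For the same reason the targeted genes could not be looked up as a check of the labels. The equatorial-enriched set was chosen after its members were seen.

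The same model was tested on simulated data with the real means and variances and 200 changed probe sets per comparison. Noise was drawn independently for each probe set and array, without a batch, in a single draw per comparison. The shares below therefore describe data without a batch or correlated probe sets. Cerberus-Short and Sox17-MO have the same group sizes, so their shares differ by the draw and not by the design. The first simulation was run after the first fit of the real data. For Cerberus-Short against control it called 61.2% of the 2-fold and 89.4% of the 3-fold changes among 15450 probe sets. For Mixer-MO against control the shares were 32.8% and 71.2%, for Sox17-MO 35.8% and 87.9%, and for vegetal against cap, before the fold minimum, 19.4% and 59.1%. False calls made up 5.13%, 6.41%, 3.30% and 8.62% of the calls in these 4 comparisons. In the others they ran from 3.45% to 13.4% (Mixer-MO against Sox17-MO, 9 false calls), with 9.84% for vegetal against equatorial, so some lists may hold more than 5% false calls.

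The array titles carry a letter code that recurs across groups. Residuals of injected and control arrays that share a letter correlated in all 7 pairs, from 0.518 to 0.852. Over all 30 pairs of arrays from different groups that share a letter, tissues and stage 18 included, the median was 0.317 and the lowest -0.216, with 7 pairs below 0. The letter was treated as a batch, less firmly outside the injected groups, and its values as a block are given beside the results it moved. Alternatives covered blocks by replicate number and title letter, the arrays in the fit, normalization, a low filter of 40%, array weights, variance trend, a pseudocount of 16, fold minimums, set definitions and leaving out each array. Overlaps were set against 50 simulations of unchanged groups with the same controls, and 50 more were run with the title letter as a fixed block, added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.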

Results

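The study profiled Xenopus laevis, the African clawed frog, on Affymetrix Xenopus arrays to define transcripts enriched in the endoderm of the gastrula and to ask how they depend on nodal signalling, Mixer and Sox17. The series holds 31 arrays in 9 groups. Stage 11 whole gastrulae served as controls (n = 9), and 3 kinds of explant, collected at stage 11, represented the tissues. These were the animal cap, which forms ectoderm (n = 3), the equatorial region (n = 2) and the vegetal region, which forms endoderm (n = 2). The caps were cut at stage 9, and the labels give no dissection stage for the other explants. Differences from the caps may therefore mix tissue with explant handling. Embryos injected at the 2-cell stage formed 3 further groups. The first received 1 ng of RNA for Cerberus-Short, a secreted protein that blocks nodal ligands (n = 3). The second received 40 ng of an antisense morpholino oligonucleotide against the homeodomain factor Mixer (n = 2), although the title of Mixer-MO replicate 1 gives 32 ng. The third received 3 morpholinos against genes of the HMG-box factor Sox17, at 20 ng each (n = 3). The labels give no injection for the controls, and no group received a control RNA or control morpholino. Effects of injection itself therefore cannot be told apart from those of each reagent. Eggs (n = 3) and stage 18 embryos (n = 4) gave the levels before and after gastrulation. A sample pooled about 20 embryos or about 50 explants. The number of arrays limits the precision of each value, and the median intensity per array averaged 72.2 ± 2.67 (SD, n = 9) in the stage 11 controls. The values are linear intensities normalized by the authors, analysed here as log2. Gene names were not used here because the tables given do not pair probe sets with genes, so probe sets are named by their identifiers.

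Vegetal and animal cap explants differed most among the tissues. Of 15450 probe sets tested, 994 were higher in vegetal explants and 1025 were lower by at least 2-fold (limma, adjusted p under 0.05). The 994 are called the endoderm-enriched set below, and the 1025 the ectoderm-enriched set. Probe set Xl.44.1.S1_s_at had a log2 level of 11.61 ± 0.05 (SD, n = 2) in vegetal explants and 4.66 ± 0.69 (SD, n = 3) in animal caps, a 124-fold difference (limma, adjusted p = 5.61e-10). Xl.1929.1.A1_at was higher in vegetal explants by log2 6.79, and by 5.28 with a pseudocount of 16, against a cap intensity of 8.42, for which signal over background was not analysed here. Xl.838.1.S1_at was 53.3-fold lower and Xl.25460.1.A1_at was 33.9-fold lower. The mean of the whole gastrulae lay between the cap and vegetal means for 949 members of the endoderm-enriched set (95.5%). The size of the set depended on vegetal replicate 2. Without that array 665 probe sets were called in either direction instead of 2019, and 440 formed the set. That array also had the highest log2 difference between the 3' and 5' probe sets for beta-actin, a measure of RNA integrity, at 1.70, against -1.50 in vegetal replicate 1. Its difference for GAPDH was 2.75, against 2.39 in vegetal replicate 1 and 2.40 ± 0.69 (SD, n = 9) in the controls.

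Equatorial explants and animal caps differed for 126 probe sets, of which 105 were higher and 21 lower in equatorial explants. Xl.1108.1.S1_at was 36.0-fold higher (log2 9.19 ± 0.33, SD, n = 2, against 4.02 ± 0.25, SD, n = 3), and Xl.642.1.S1_at was 35.2-fold higher. Xl.620.1.S1_at was 12.7-fold lower and Xl.620.1.S1_s_at 11.7-fold lower, and they lost their calls in 2 of 17 and 3 of 19 alternatives. Both risers belong to the endoderm-enriched set, of which 83 members were higher in equatorial explants than in caps. Without equatorial replicate 2 the count of calls was 68, and without replicate 1 it was 74.

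Vegetal explants stood above equatorial ones for 367 probe sets and below them for 372. Xl.7252.1.S1_at was higher (log2 8.92 ± 0.17, SD, n = 2, against 2.58 ± 0.04, SD, n = 2), and Xl.14891.1.S1_at was 38.5-fold higher. Xl.838.1.S1_at was 26.8-fold lower, and Xl.15579.1.S1_at was also lower. The lower intensities were 5.97 for Xl.7252.1.S1_at and 5.98 for Xl.15579.1.S1_at, near the lowest value of 3.52, so the size of these 2 differences is uncertain. Over the alternatives their log2 differences ran from 4.51 to 6.70 and from -4.38 to -2.55, the smallest in size with the pseudocount. Within the endoderm-enriched set, 320 members were also higher in vegetal than in equatorial explants. The count of 739 calls rose to 1349 with the letter code in the array titles as a fixed block and to 1512 with it as a random block. It fell to 295 without vegetal replicate 2, to 276 without equatorial replicate 2 and to 325 without equatorial replicate 1.

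**Figure D1:**
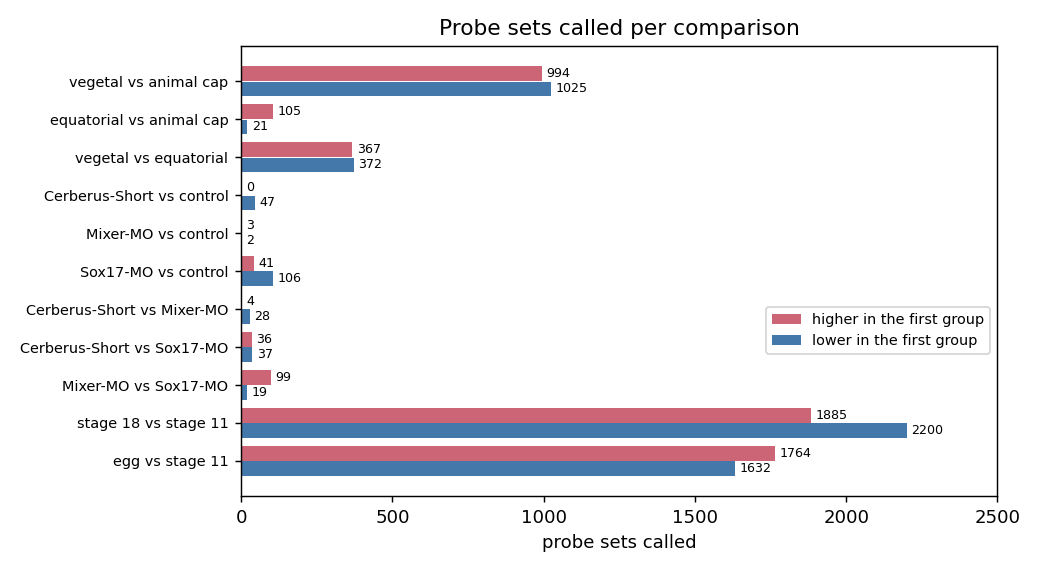
Number of probe sets called higher (red) and lower (blue) in the first-named group of each of the 11 comparisons; the axis counts probe sets. The stage 18 comparison gave 4085 calls and the Mixer-MO comparison 5.

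Cerberus-Short lowered part of the endoderm-enriched set and raised no probe set past the threshold. In injected gastrulae 47 probe sets were lower and 0 higher than in controls (limma; 322 had an unadjusted p under 0.05). All 47 belonged to the endoderm-enriched set, 4.73% of its members, against 0 of the 14456 other probe sets (Fisher's exact test, adjusted p = 1.13e-55). Xl.6024.1.S1_at was 9.03-fold lower, at log2 3.85 ± 0.68 (SD, n = 3) against 7.02 ± 0.50 (SD, n = 9), and Xl.1108.1.S1_at was 8.95-fold lower, at log2 6.09 ± 1.76 (SD, n = 3) against 9.25 ± 0.55 (SD, n = 9). The log2 difference of Xl.1108.1.S1_at ran from -3.71 without Cerberus-Short replicate 2 to -2.15 without replicate 3. Adjusted over the list alone, 87 members were lower, though the set was chosen on arrays of the same series. On average the set moved down (camera, adjusted p = 1.86e-21 with a preset correlation and adjusted p = 0.0188 with an estimated correlation). Before adjustment, its shift did not reach 0.05 with fry. The fall was uneven. The 202 members lower in the egg than at stage 11 had a median log2 change of -0.735. The median was -0.0967 in the 594 members not called in the egg comparison and -0.00407 in the 198 higher in the egg. The set's mean score per array, the mean log2 level relative to controls, was -0.25 ± 0.14 (SD, n = 3) against 0.00 ± 0.19 (SD, n = 9). That gave a two-sided exact permutation p = 0.0636, with an adjusted p = 0.164 over 9 scores. The score was lower than in the control of the same title letter in 3 of 3 pairs, by -0.16, -0.29 and -0.17. In these pairs 49.3%, 61.1% and 61.0% of the members were lower than in the control. Without Cerberus-Short replicate 3 the set count was 26, and fitted on these groups alone it was 27.

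**Figure D2:**
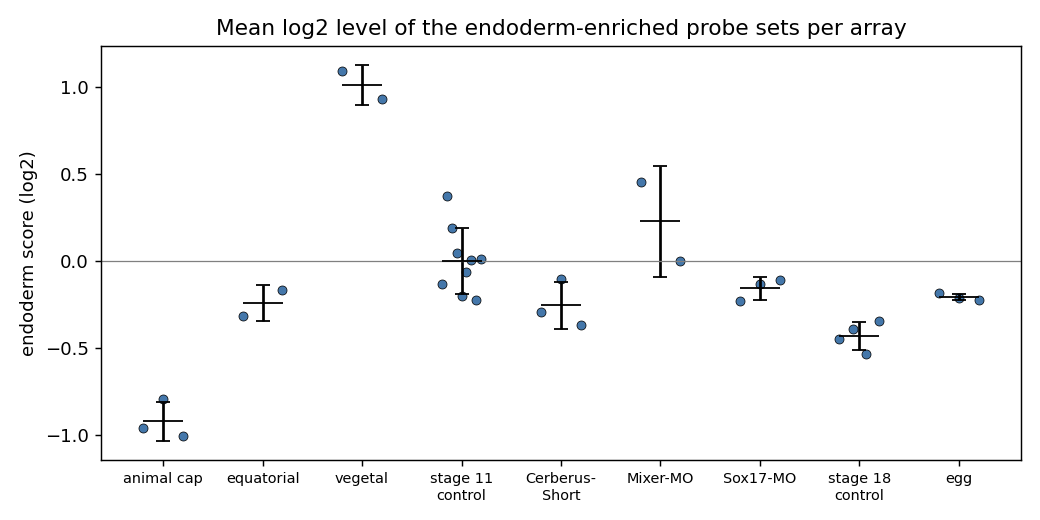
Endoderm score of each of the 31 arrays by group, in log2 units relative to the stage 11 control mean; points are arrays, and bars give the mean and SD. Vegetal explants averaged 1.01, animal caps -0.92 and Cerberus-Short embryos -0.25.

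The Mixer morpholino changed few probe sets past the threshold. Compared with controls, 3 were higher and 2 lower (limma; 1251 had an unadjusted p under 0.05). Xl.6024.1.S1_at was 5.77-fold lower, at log2 4.49 ± 0.93 (SD, n = 2) against 7.02 ± 0.50 (SD, n = 9), and Xl.1627.1.A1_at was 2.38-fold lower; they lost their calls in 3 and 5 of 26 alternatives. Xl.10200.1.A1_at was 3.92-fold higher (limma, adjusted p = 0.0166) and lost its call in 7 of 26 alternatives. Xl.7751.1.S1_at was 4.88-fold higher (limma, adjusted p = 0.0499) and lost its call in 17 of 26, among them quantile normalization, median centring and the removal of either Mixer-MO array or of control replicate 2, 3, 4, 5, 6, 8 or 9. In the endoderm-enriched set 1 member was lower and 1 higher, and adjusted over the list alone 7 were lower and 8 higher. The set's score was higher by 0.23 than in controls (exact permutation p = 0.182). Its upward shift passed with a preset correlation (camera, adjusted p = 4.14e-09) and not with an estimated one (adjusted p = 0.179 with an estimated correlation), as did the downward shift of the ectoderm-enriched set (adjusted p = 7.76e-18 and adjusted p = 0.135). Mixer-MO replicate 2 had a score of 0.45 and its control of the same title letter, J, a score of 0.37, while Mixer-MO replicate 1 had a score of 0.00. In the J pair 30.5% of the members were lower than in the control. The ectoderm score averaged -0.43 ± 0.52 (SD, n = 2; exact permutation p = 0.0727), with -0.80 in Mixer-MO replicate 2, -0.58 in the J control and -0.07 in Mixer-MO replicate 1. Both J arrays also had high beta-actin 3' to 5' differences, at 1.49 and 0.90 against a control mean of -2.19 ± 1.48 (SD, n = 9), and GAPDH differences of 3.60 and 3.90 against 2.40 ± 0.69 (SD, n = 9). With the title letter as a fixed block, where only the J pair bears on the contrast, 0 probe sets were called. With the titles of Mixer-MO replicate 1 and control replicate 8, which carry no letter, joined as 1 code there were 5, and with the letter as a random block 8, of which 2 were lower members of the set. The count was 0 without Mixer-MO replicate 1, 2 without Mixer-MO replicate 2 and 20 without control replicate 7, a J array.

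The Sox17 morpholinos lowered more probe sets than they raised. In injected gastrulae 106 were lower and 41 higher than in controls. Xl.15758.1.A1_at, a member of the endoderm-enriched set, was 5.68-fold lower, at log2 4.53 ± 0.44 (SD, n = 3) against 7.04 ± 0.77 (SD, n = 9), and Xl.960.1.S1_at, a member of the ectoderm-enriched set, was 4.39-fold lower. Xl.21079.1.S1_at was 5.62-fold higher and Xl.15745.1.A1_at was 5.01-fold higher. Without Sox17-MO replicate 3 neither these 2 nor Xl.15758.1.A1_at kept the call. In the endoderm-enriched set 16 members were lower (1.61%, against 0.623% of the other probe sets; Fisher's exact test, adjusted p = 0.00270) and 5 higher. Adjusted over the list alone, 28 were lower and 10 higher. The set-wide shift passed with a preset correlation (camera, adjusted p = 1.09e-05) and not with an estimated one (adjusted p = 0.255 with an estimated correlation). The score was -0.16 ± 0.06 (SD, n = 3; exact permutation p = 0.195) and lay below the control of the same title letter in 3 of 3 pairs, by -0.18 to -0.05. In these pairs (letters f, G and C) the GAPDH 3' to 5' difference was also lower, at 1.80, 1.97 and 0.92 against 3.04, 2.47 and 1.65. For beta-actin it was -2.27, -2.44 and -3.38 against -0.39, -2.68 and -2.95. A link between these differences and the score was not tested in these pairs. The count of 147 calls fell to 16 without Sox17-MO replicate 3 and to 45 without replicate 2, and rose to 295 with the title letter as a random block and to 428 with array weights. The 16 lower members of the set became 38 with the random block, 2 without Sox17-MO replicate 3, 6 without replicate 2, and 10 without vegetal replicate 2 or animal cap replicate 1, which changes the set.

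**Figure D3:**
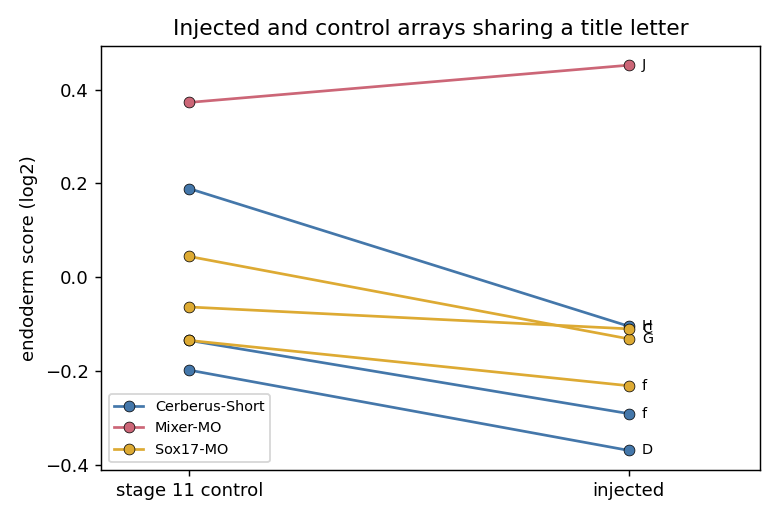
Endoderm score (log2 relative to the stage 11 control mean) of each injected array and of the control array that shares its title letter; lines join the 7 pairs. The 3 Cerberus-Short and 3 Sox17-MO lines descend, and the Mixer-MO line of code J starts at 0.37 and ends at 0.45.

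Direct comparisons tested whether the interventions differed. Cerberus-Short embryos had 28 probe sets lower and 4 higher than Mixer-MO embryos, with Xl.801.1.S1_at 15.3-fold lower and Xl.13110.1.A1_at 5.22-fold higher. These lost their calls in 6 of 19 and 13 of 20 alternatives, the second with quantile normalization and with the title letter as a random block. Of the 46 set members called lower with Cerberus-Short and not with Mixer-MO, 16 were also lower in this direct test. Against Sox17-MO embryos, 37 were lower and 36 higher, with Xl.579.1.S1_at 6.61-fold lower and Xl.960.1.S1_at 4.75-fold higher, each losing its call in 1 of 20 alternatives. Of the 43 members called lower with Cerberus-Short and not with the Sox17 morpholinos, 19 were also lower in the direct test. Mixer-MO embryos had 99 probe sets higher and 19 lower than Sox17-MO embryos, with Xl.397.1.S1_at 11.6-fold higher and Xl.8440.1.S1_at 9.53-fold lower. The first lost its call in 9 of 19 alternatives and the second in 12 of 20, among them quantile normalization and the random block. With the title letter as a fixed block, both comparisons with Mixer-MO gave 0 calls, and fitted on the 2 compared groups alone all 3 gave 0. Cerberus-Short against Mixer-MO gave 19 calls without Cerberus-Short replicate 2, 172 without its replicate 3, and 6 and 2 without Mixer-MO replicates 1 and 2. Cerberus-Short against Sox17-MO gave 46 and 36 without Cerberus-Short replicates 1 and 2, and 34 and 12 without Sox17-MO replicates 2 and 3, and 163 with the title letter as a random block. Mixer-MO against Sox17-MO gave 8 and 0 without Mixer-MO replicates 1 and 2, 184, 23 and 19 without Sox17-MO replicates 1, 2 and 3, and 58 with the random block.

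Few probe sets were called with more than 1 intervention. Cerberus-Short and the Sox17 morpholinos shared 4 lower probe sets, all in the endoderm-enriched set, where independent lists would share 0.757. Cerberus-Short and the Mixer morpholino shared 1, and the Mixer and Sox17 morpholinos shared 1 that was higher. With separate controls for each intervention, the overlap of Cerberus-Short and Sox17-MO was 1, 1 and 0 in 3 assignments of the controls. Each comparison then had 3 of the 9 controls, assigned by replicate number and not by title letter. Lost power may lower this overlap as well as the separation of controls. With shared controls the overlap was 1 without Sox17-MO replicate 2 or 3 and 7 without control replicate 6. With the title letter as a random block the pairs shared 2, 11 and 3 calls, in the order Cerberus-Short and Mixer-MO, Cerberus-Short and Sox17-MO, Mixer-MO and Sox17-MO, and with it as a fixed block the pairs with Mixer-MO shared 0. Over the set, log2 changes with Cerberus-Short and the Sox17 morpholinos correlated at r = 0.276 across probe sets, which are not independent replicates, where simulated unchanged groups gave 0.256. Their covariance was 0.0694 against a simulated 0.0232, and with separate controls from 0.0415 to 0.0718, with correlations from 0.133 to 0.276. For Cerberus-Short and Mixer-MO the correlation was 0.345 against a simulated 0.213, and the covariance 0.111 against 0.0227 (0.257 to 0.295 and 0.0842 to 0.103 with separate controls). For Mixer-MO and Sox17-MO they were 0.221 against 0.220, and 0.0587 against 0.0234 (0.0905 to 0.214 and 0.0272 to 0.0626 with separate controls). Over all 15450 probe sets the correlations were -0.104, 0.211 and -0.103 in the order of pairs given for the shared calls, against simulated values of 0.212, 0.250 and 0.215, and the covariances -0.0123, 0.0197 and -0.0158 against 0.0218, 0.0219 and 0.0220. With separate controls these correlations ran from -0.479 to 0.104, from -0.275 to 0.197 and from -0.332 to -0.0786, so the sign of the first 2 depended on the controls used. The covariances ran from -0.0958 to 0.0186, from -0.0470 to 0.0228 and from -0.0704 to -0.0125. With the title letter as a fixed block, the set gave, in that order, correlations of 0.474, 0.356 and 0.361 where simulated unchanged groups in that design gave -0.00120, 0.195 and 0.00176, and covariances of 0.103, 0.0923 and 0.0695 against -0.000180, 0.0146 and 0.000265. All probe sets then gave correlations of 0.0567, 0.156 and 0.158 against 0.000998, 0.194 and 0.00170. The spread over the simulations was not analysed here, and members of the set correlate with one another (0.125 as estimated by camera). How far unchanged groups could lie from the simulated values is therefore open, and no shared response is inferred from these differences.

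Stage 18 embryos differed from stage 11 gastrulae for 4085 probe sets, 1885 higher and 2200 lower by at least 2-fold. Xl.1055.1.S1_s_at was 111-fold higher, at log2 10.02 ± 0.45 (SD, n = 4) against 3.24 ± 0.63 (SD, n = 9), and Xl.6263.1.S1_at was 108-fold higher. Xl.1289.1.S1_at was 70.8-fold lower and Xl.824.1.S1_at, a member of the endoderm-enriched set, was 39.2-fold lower. In that set 272 members were lower at stage 18 and 93 higher (27.4% lower, against 13.3% of the other probe sets; Fisher's exact test, adjusted p = 3.48e-28). The shift of the set as a whole passed with a preset correlation (camera, adjusted p = 7.34e-05) and not with an estimated one (adjusted p = 0.344 with an estimated correlation).

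Eggs had 1764 probe sets higher and 1632 lower than stage 11 gastrulae by at least 2-fold. All eggs carry a title letter that no other group has, so egg and title letter cannot be told apart here. Xl.5300.1.A1_at was 92.3-fold higher, at log2 10.28 ± 0.27 (SD, n = 3) against 3.75 ± 0.58 (SD, n = 9), and Xl.1244.1.S1_at was 40.1-fold higher. Xl.3454.1.S1_at was 144-fold lower and Xl.21426.1.S1_at was 133-fold lower. The endoderm-enriched set split almost evenly, with 198 members higher in the egg, 202 lower and 594 not called. All 47 members that were lower with Cerberus-Short were among the 202 that were lower in the egg (23.3%), against 0 of the 792 others (Fisher's exact test across probe sets, adjusted p = 8.04e-35). With the Sox17 morpholinos 8 of the 202 were lower (3.96%), against 8 of the 792 others (1.01%; adjusted p = 0.0109), and with the Mixer morpholino 1 and 0.

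**Figure D4:**
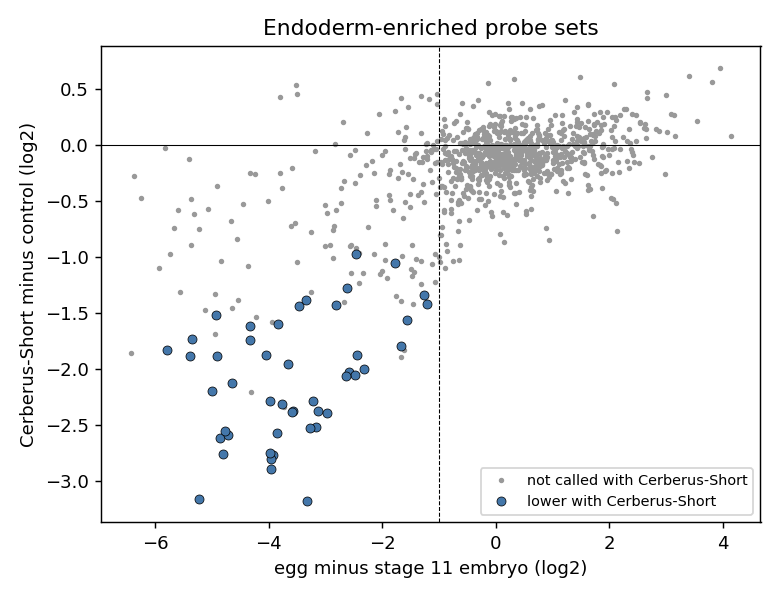
Log2 change with Cerberus-Short against controls (vertical) and log2 difference between egg and stage 11 gastrula (horizontal) for the 994 endoderm-enriched probe sets; the dashed line marks -1. The 47 called lower with Cerberus-Short (blue) all lie left of that line.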

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

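The tests of the title letter and of the actin 3' to 5' difference for the Mixer morpholino were chosen after their results were seen, the interval for vegetal replicate 1 was added after its share was seen, and the values with equal weight per bin, of single bins and of 20 bins were added after the weighted difference was seen. Of 86 combinations of a control group and a measure, 9 had 1 array standing apart from the rest of its group by Dixon's test, where chance gives about 1 in 20. In the stage 11 controls (n = 9), replicate 7 had an ectoderm score of -0.58, against -0.13 to 0.31 in the others. Replicate 9 had a log2 level of 4.88 for Xl.1055.1.S1_s_at, against 2.88 to 3.21, and of 9.80 for Xl.1289.1.S1_at, against 10.67 to 11.32. In the stage 18 controls (n = 4), replicate 2 had a beta-actin 3' to 5' difference of 0.38, against -2.45 to -2.03, and a level of 5.29 for Xl.642.1.S1_at, against 6.10 to 6.25. Replicate 4 had a GAPDH 3' to 5' difference of 1.84, against 3.38 to 3.60, a level of 7.09 for Xl.1627.1.A1_at, against 7.41 to 7.46, and a level of 10.01 for Xl.9051.1.S1_at, against 9.40 to 9.48. Replicate 1 had a level of 9.35 for Xl.1055.1.S1_s_at, against 10.19 to 10.31.

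The Mixer morpholino arrays averaged a higher endoderm score than controls, by 0.23, and a lower ectoderm score, at -0.43. A title letter batch may account for part of the endoderm score: within code J the difference was 0.0794 (-0.22 for the ectoderm score), and the other Mixer-MO array scored 0.00. In the J pair, however, 30.5% of the members were lower than in the control and most were higher, so the letter may not account for all of it. RNA integrity is a second candidate explanation. Over the 9 controls the score and the beta-actin 3' to 5' difference had a Pearson r of 0.629 (exact permutation p = 0.0699) and a Spearman rho of 0.650 (exact permutation p = 0.0666), and without the 2 farthest arrays, replicates 7 and 9, r was 0.833 (exact permutation p = 0.0274, n = 7). Of the arrays left out, control replicate 7 had a beta-actin difference of 0.90 and an endoderm score of 0.37. Control replicate 9 went against the relation, with a difference of -0.39 and a score of -0.13. The beta-actin ratio was under 1 on 26 arrays, so it is an uncertain measure of integrity. An effect of the morpholino stays open, since code J holds 1 array of each group.

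The members lowered by Cerberus-Short were all lower in the egg than at stage 11; both comparisons use the same controls, but with separate controls 42 of 190 members lower in the egg were called lower, against 0 of 804 others (Fisher's exact test, p = 1.17e-32), which argues against shared controls as the cause. Larger vegetal to cap folds of the members lower in the egg did not account for all of it: within 4 equal bins of that fold, weighted by these members, their mean log2 change differed from that of the others by -0.768, against -0.805 without the bins (permutation p = 0.0001, the smallest that 10000 permutations can give). With equal weight per bin it was -0.433, and with 20 bins -0.764 weighted and -0.378 unweighted (permutation p = 0.0001 each). The last was 47.0% of the difference without bins, so the share that follows the fold is uncertain. From the lowest to the highest folds the differences were -0.0716 (permutation p = 0.091), -0.262, -0.290 and -1.11 (permutation p = 0.0001 each), so most of it lay in the highest bin, with 124 of these 202 members. In that bin the median fold was log2 3.77 for these members and 2.54 for the others, so the bin did not hold the fold constant. In the bin with -0.262 the medians were close, at 1.36 and 1.37. No biological explanation was tested.

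The endoderm-enriched set shrank from 994 to 440 without vegetal replicate 2, the array with the highest beta-actin 3' to 5' difference, while its GAPDH difference of 2.75 lay within the spread of the controls (2.40 ± 0.69, SD, n = 9). Of the 994 members, 80.2% (exact binomial 95% interval 77.6 to 82.6) were at least 2-fold above the caps in vegetal replicate 1 alone, where 80% had been set as the bound against RNA integrity as the source, so integrity and tissue cannot be told apart for the set's size; members were chosen on both arrays, which also favours the share. The set made without that array held 47 probe sets that were lower with Cerberus-Short.

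Other splits of the samples were counted for the 5 comparisons between groups of at least 3 arrays. For Cerberus-Short, Sox17-MO and the egg 100 of 220 possible splits were drawn, and for stage 18 100 of 715. Over these splits, which ignore the title letter, only the real one reached its count for stage 18 and for the egg (1 of 100 each). That share measures chance only if arrays of different letters can be exchanged. The splits do not separate egg from title letter, since all eggs share a letter of their own. For Cerberus-Short and Sox17-MO the splits cannot exclude chance, since residuals of injected and control arrays that share a letter correlate. For Cerberus-Short, 3 of 100 splits called as many probe sets as the real 47, and the highest other called 1432. That split joined 2 arrays of code H with the control of code J, and the other as large held 2 arrays of code D, so the samples have a structure by title letter. In the endoderm-enriched set 1 of 100 splits, the real one, gave 47, and the highest other gave 30. When injected and control arrays were exchanged within letters, the other 7 of 8 arrangements called 0 (limma), but 8 are too few for a share under 0.05 (the smallest is 0.125). With the letter as a fixed block 35 probe sets were called, 34 of them lower in the set. For Sox17-MO, 1 of 100 splits, the real one, reached 147, with 140 the highest other (Sox17-MO replicates 2 and 3 with the control of code f). In the set it gave 16 against 14, and the 7 exchanges within letters, under the same limit, called 0; with the fixed block 149 were called and 18 were lower in the set. The real split alone gave the 4085 calls at stage 18 (highest other 2844) and the 3396 in the egg (highest other 673). Cerberus-Short against Sox17-MO has 10 splits, too few for a share under 0.05; it gave 73 calls and the highest other 0.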

How the results depend on the processing

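Alternatives were listed before the data were examined, except the joined title code, the probe sets with undecided values kept, 1 probe set per identifier stem, the sets built from single arrays, the egg and intervention comparisons with different controls, and the removal of the J arrays, which were added after seeing the data. For the shared calls and the egg level, counts beyond the listed thresholds, separate controls, filter and normalization come from fits listed for the comparisons themselves. The joined code was tried after the 2 arrays' correlation of 0.505 was seen. One probe set per gene symbol and the gene list alternatives were not run, for want of gene names. Of the alternative counts per comparison, 359 stayed within 1.5 times the main count and 141 did not. Of 910 alternative values of the 42 named probe sets, 782 kept direction and call, 128 lost the call and 0 reversed. Except where stated, the cause was not tested. Signal over background was not analysed here.

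Replicate numbers do not pair the arrays (residual correlations from -0.480 to 0.454 in 8 pairs, 0 of 8 injected arrays closest to their own number). With the replicate block Mixer-MO gave 150 calls (7 lower in the set), Sox17-MO 26 (4) and Mixer-MO against Sox17-MO 309; shared calls of Mixer-MO were 2 with Cerberus-Short and 4 with Sox17-MO. With the title letter as a random block, vegetal against equatorial gave 1512, Mixer-MO 8 (2), Sox17-MO 295 (38), Cerberus-Short against Sox17-MO 163 and Mixer-MO against Sox17-MO 58, and the shared calls were 2, 11 and 3. As a fixed block it gave 1349 for vegetal against equatorial and 0 for Mixer-MO, its set count, its 2 direct comparisons and its shared calls. With the joined code these were 1527, 5 for Mixer-MO, 2 in the set, 0 in the direct comparisons and 2 shared with each intervention. The egg comparison has no fixed letter block, since its letter occurs in no other group.

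Fitted on the groups compared alone, with fewer samples for the spread, vegetal against equatorial gave 199, Cerberus-Short 27 (27 in the set), and Mixer-MO, its set count, the 3 direct comparisons and the shared calls with Mixer-MO 0. On stage 11 arrays alone Mixer-MO gave 2, and its comparisons with Cerberus-Short and Sox17-MO 17 and 60, with 0 shared with Sox17-MO. Quantile normalization gave 18 for Cerberus-Short against Mixer-MO, 2 for Mixer-MO in the set and 2 shared. Median centring left 0 shared between Mixer-MO and Sox17-MO, and the low filter 2 between Cerberus-Short and Sox17-MO. Array weights gave 313 for equatorial against cap, 428 for Sox17-MO (49), 2 for Mixer-MO in the set, 150 and 237 for Sox17-MO against Cerberus-Short and Mixer-MO, and 2, 9 and 2 shared calls. Mixer-MO gave 10 with the pseudocount, with undecided probe sets kept (2 in the set) and with 1 probe set per stem (2 in the set). Without the J arrays it gave 2, its direct comparisons 5 and 0, and 0 shared with Sox17-MO.

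A fold minimum of 3 left 1124 calls for vegetal against cap and a set of 471 members, of which 9 were lower with Sox17-MO. At stage 18 a fold minimum of 1.5 gave 6582 and none 7472. In the set above cap and equatorial (320 members), 28 were lower with Cerberus-Short (8.75%), 7 with Sox17-MO (2.19%) and 71 in the egg. In the set from the mean of vegetal and equatorial (389 members), 47 were lower with Cerberus-Short and 9 with Sox17-MO. The set called without any 1 vegetal or cap array kept 337 of the 994 members. Of these, 45 were lower with Cerberus-Short, 10 with Sox17-MO and 125 in the egg. These sets are smaller than the main one, so a lower count need not be a lower share. At an adjusted p under 0.01, shared calls of Sox17-MO were 2 with Cerberus-Short and 0 with Mixer-MO, and under 0.10 the shared calls were 2, 10 and 2. With separate controls they were 0, 1 and 0, then 0, 1 and 0, then 0, 0 and 0.

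Leaving out 1 array gave 30 to 57 calls for Cerberus-Short (26 to 54 in the set; both lowest without its replicate 3), 0 to 20 for Mixer-MO (0 to 3 in the set; 2 without its replicate 2, 0 without replicate 1) and 16 to 142 for Sox17-MO (2 to 20 in the set; lowest without its replicate 3). It gave 665 to 2245 for vegetal against cap, 68 to 114 for equatorial against cap, 276 to 1024 for vegetal against equatorial, 2 to 172 for Cerberus-Short against Mixer-MO, 12 to 88 for Cerberus-Short against Sox17-MO and 0 to 184 for Mixer-MO against Sox17-MO. Shared calls ran from 0 to 2, 1 to 7 and 0 to 2. The arrays whose removal moved a count beyond 1.5 times were those named with the comparisons, and for the set count of Mixer-MO its replicate 1 (0) and control replicates 6 (2) and 7 (3). Shared calls of Cerberus-Short and Mixer-MO moved without Cerberus-Short replicate 3 (2) or Mixer-MO replicate 1 (0). Shared calls of Mixer-MO and Sox17-MO were 0 without either Mixer-MO array, Sox17-MO replicate 2 or 3, or control replicate 2, 3, 4, 5, 6, 8 or 9, and 2 without control replicate 7. Where 1 array was left in a group, it was assumed to vary like the other groups. No single array moved the stage 18, egg or egg-level counts beyond 1.5 times.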

Other observations

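All tests of the equatorial-enriched set were chosen after the data were seen. A set of 11 probe sets was higher in equatorial explants than in both caps and vegetal explants, and 10 of the 11 were lower in the egg than at stage 11 (limma). With the Sox17 morpholinos its mean score was -0.68 ± 0.27 (SD, n = 3) against 0.00 ± 0.22 (SD, n = 9) in controls, with an exact permutation p = 0.00455, the smallest the design allows, and an adjusted p = 0.0409 over 9 scores. The score was below the control of the same title letter in 3 of 3 pairs, and 1 member passed the test over all probe sets and 6 the test over the set alone. Without 1 array the difference ran from -0.78 to -0.53, with exact permutation p-values up to 0.0182. These permutations ignore the title letter, although residuals of injected and control arrays that share a letter correlate. Exchange within letters has 8 arrangements for Sox17-MO, too few for a share under 0.05 (the smallest is 0.125). Chance is therefore not excluded for this score. With Cerberus-Short the difference was -0.19 (exact permutation p = 0.318) and with the Mixer morpholino -0.33 (exact permutation p = 0.0727). Cerberus-Short and Sox17-MO embryos differed for this set (camera, adjusted p = 0.0453 with an estimated correlation).

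Between the egg, stage 11 and stage 18, 75 endoderm-enriched probe sets were lower at both ends than at stage 11, 57 were higher in the egg and lower at stage 18, 34 were lower in the egg and higher at stage 18, and 4 were higher at both.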
